A study of Homo sapiens with 6 samples.

How the data were processed

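Single-cell RNA was measured in IMR-90, an established line of human lung fibroblasts, with the Chromium 3' v3.1 droplet assay, which tags each captured RNA molecule with a unique molecular identifier (UMI). Per the labels' protocols, cultures received 4 Gy of hydrogen ions, silicon ions, iron ions or gamma rays from a 137Cs source and rested for a further 13 days after shipment back, to let senescence develop. The labels also name a mock control for the irradiation and a healthy low-passage control, whose handling is not described apart. For the mock and irradiated groups, 3 replicate cultures were pooled before capture, at a viability above 80%. About 10000 cells were loaded for each library and about 20000 reads per cell were sought, so the data hold 6 libraries, 1 per group.

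The deposited matrices hold counts: whole-number UMI counts of 36601 genes in the cell barcodes the authors kept, with no normalization. Per the labels' protocols, reads were mapped to the prebuilt GRCh38 reference with Cell Ranger 5.0.0 at default settings, while per the file headers the matrices came from Cell Ranger 7.0.1. By default the later release also counts reads from introns, and which release gave these counts was taken from the file headers. The submitters' processing notes name Seurat 5.0 and GRCh38, and no table from that step was deposited for use here. Positions of named genes were looked up by Ensembl gene ID in GENCODE 44 on GRCh38, and genes named without a position had no match there.

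Barcodes with at least 500 detected genes and at most 15% of UMIs from mitochondrial genes were kept. Doublets were kept, since doublets within 1 line mostly join like cells. Scrublet scores, run through scanpy 1.11.5, served an alternative only. The automatic Scrublet threshold called 0 to 4 barcodes per library and so did not separate doublets, and the alternative therefore removed the highest scores at a rate that grows with the number of cells, from 1.54% in silicon to 9.48% in iron. This took out 522 healthy, 707 mock, 528 hydrogen, 261 gamma, 30 silicon and 1123 iron barcodes.

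UMIs were summed over the kept cells of each library and scaled to the library's total UMIs as CPM. Each ratio of 2 libraries carries an exact 95% interval for a ratio of 2 Poisson counts (conditional Clopper-Pearson). These intervals cover counting error only. With 1 library per group no spread between replicates exists and cells are not replicates, so no test was run, no p-value was computed, and every difference between libraries lacks a replicate check. A gene at 0 counts was compared at a floor of 3 counts in its library, and no fold was given where both libraries were at or under the floor. Ratios were tested on simulated data in which both libraries were drawn from the control's profile and 200 genes were given known folds of 4, 2, 0.5 or 0.25. The median recovered fold was between 3.99 and 4.01 for a true fold of 4 and between 1.98 and 2.01 for a true fold of 2. Over the genes left unchanged, 0 were 2-fold apart, and 95.0% to 95.4% of the intervals held a ratio of 1. The simulated counts were Poisson counts, as the intervals assume, so this checks the computation and not the spread of real libraries.

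The comparisons were each irradiated library against mock, mock against healthy, each irradiated library against healthy, all 4 irradiated libraries against both controls, each irradiated library against the other 3, and silicon and iron against gamma and hydrogen. Genes at least 2-fold apart were counted among those with at least 10 CPM in 1 or both libraries, or in at least 1 of the libraries when more were compared. Each irradiated library against the other 3 used the floor and exclusions of the rule for named genes. The number of genes shared by all 4 irradiated libraries was set beside the number that independent libraries would give and beside 20 simulations in which the irradiated libraries differed from mock by counting only. For silicon and iron against gamma and hydrogen, a gene was counted when both libraries of either pair lay above both of the other. Chance gives this for 33.3% of genes if every order of the libraries is equally likely.

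For 31 gene lists of 7 to 30 members, the median log2 ratio over the detected members (at least 5 CPM in 1 or both libraries) and the members at least 1.5-fold higher or lower were computed. Each median was placed as a percentile among 10000 random lists of the same size matched over 20 bins of mean expression, as a description and not a test. The lists cover the G1/S and G2/M cell cycle, p53 targets, cyclin-dependent kinase inhibitors, secreted cytokines, matrix proteases, secreted growth factors, nuclear lamina and chromatin, DNA double-strand break repair, interferon-stimulated genes, the cGAS-STING pathway, MHC class I, collagens, myofibroblast genes, YAP and TEAD targets, cholesterol synthesis, ATF4 and the unfolded protein response, hypoxia and glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, oxidative stress, metallothioneins, lysosome, the BCL-2 family, immediate early and heat shock genes, ribosomal proteins, and markers of epithelial, endothelial, blood and immune cells, pericytes and fibroblasts.

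The genes named in the text follow a rule. It leaves out mitochondrial and ribosomal protein genes outside the lists, sex-linked marker genes and genes with clone names, and asks for at least 20 CPM in 1 or more of the libraries compared. It takes the 10 genes in each direction whose smallest log2 ratio over the 8 ratios of irradiated libraries to controls was largest, the 10 largest mock to healthy ratios in each direction, the 5 genes furthest above and below the nearest of the other 3 libraries for each radiation, and the 10 largest gaps in each direction between silicon and iron and the other pair. It adds senescence-related genes chosen in advance (among them CDKN1A, CDKN2A, CDKN2B, LMNB1, MKI67, TOP2A, GDF15, MDM2, IL6, CXCL8, CCL2, IL1B, MMP1, MMP3, IGFBP3, HMGB2, COL1A1, ACTA2), and for each list up to 4 detected members with the largest ratios and members that go against the list. Where the 4 irradiated libraries are described together, list members were ranked by the mean of their 4 log2 ratios over mock. Some genes that the rule takes are not reported here.

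Shares of cells with a UMI were taken after thinning each cell to 3000 UMIs, with shallower cells left out, and carry exact 95% Clopper-Pearson intervals. A cell counted as positive for the G2/M list with 3 or more of its members. Cells of all libraries were clustered together without batch integration (scanpy 1.11.5, counts per 10000, log of 1 plus the value, 2000 variable genes without mitochondrial and ribosomal protein genes, 30 principal components, 15 neighbours, Leiden resolution 0.5 with leidenalg 0.10.2). Clusters were named from marker sets by their 10 top genes, and the abundance asked of these genes (50 CPM and 20 counts) was set after the data were seen.

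The groups, lists, comparisons, gene rule, filters and a set of alternatives were chosen before the data were examined. The alternatives were edgeR 4.0.16 TMM scaling, DESeq2 1.42.0 median-of-ratios scaling, a total without mitochondrial and ribosomal protein genes, no cell filter, a filter of 2000 genes and 10% mitochondrial UMIs, removal of high doublet scores, cells weighted equally, thinning to 3000 UMIs, leaving out cells with 2 or more UMIs over the G1/S and G2/M lists, floors of 5 and 50 CPM, healthy as the control, no thinning or thinning to 1500 UMIs for shares, 2 or more G2/M genes, and Leiden resolutions of 0.3 and 1. After the data were seen, barcodes with under 4% of UMIs from ribosomal protein genes were called nucleus-like, and other barcodes with under 0.3% of UMIs from the nuclear RNA MALAT1 were called MALAT1-poor. Results were then recomputed without both kinds, without nucleus-like barcodes, without the silicon library and without the gamma library, and the pairings of irradiated libraries under the TMM and median-of-ratios scalings. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3. Sequence reads and the barcodes that the authors had already left out were not used here.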

Results

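The data are UMI counts of single cells from 6 libraries of IMR-90 lung fibroblasts, 1 library for each of 6 groups. The groups are a healthy low-passage culture, a mock-irradiated culture, and cultures given 4 Gy of hydrogen ions (linear energy transfer 0.5 keV/µm, 150 MeV/n), gamma rays, silicon ions (79 keV/µm, 238 MeV/n) or iron ions (174 keV/µm, 600 MeV/n). The series title gives as its subject the senescent states that follow different kinds of space radiation. After filtering, the healthy library held 8075 cells and 63488356 UMIs, mock 9404 cells and 117656247 UMIs, hydrogen 8127 cells and 68633456 UMIs, gamma 5709 cells and 33686270 UMIs, silicon 1931 cells and 12908258 UMIs, and iron 11850 cells and 72821105 UMIs. Median depth per cell was 6382 UMIs in healthy, 9941.5 in mock, 6335 in hydrogen, 5337 in gamma, 5399 in silicon and 2750 in iron. There are no replicate libraries, so every value below stands for 1 library, intervals are 95% intervals for counting error, and no difference has a replicate check.

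The libraries differed in the make-up of their barcodes. In gamma, 45.5% of barcodes (interval 44.2 to 46.8) had under 4% of UMIs from ribosomal protein genes, whose mRNAs are among the most abundant in the cytoplasm. The share of such nucleus-like barcodes was 22.2% in silicon and 16.3% in iron, against 1.49% in hydrogen, 1.94% in mock and 1.23% in healthy. In gamma the nuclear RNA MALAT1 took a median of 8.24% of UMIs in these barcodes and 2.40% in the other cells. Their median mitochondrial share of UMIs was not low, at 3.95% against 2.49% over all kept gamma barcodes. It was also above the library's median in silicon, iron, mock and healthy, but below it in hydrogen (2.96% against 4.94%). The name nucleus-like therefore describes ribosomal protein UMIs and MALAT1 only, and what these barcodes are was not tested. MALAT1-poor barcodes made up 51.0% of silicon (interval 48.7 to 53.2), 9.65% of gamma, 6.63% of iron and 4.96% of hydrogen, against 2.03% of mock and 1.98% of healthy. Leaving out both kinds kept 519 silicon, 2558 gamma, 9128 iron, 7603 hydrogen, 9031 mock and 7816 healthy cells, here called the remaining cells, and list medians, gaps and ratios of genes chosen in advance are given in them where they differ in direction or by over 1.5 times, for comparisons with mock and between irradiated libraries.

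**Figure D1:**
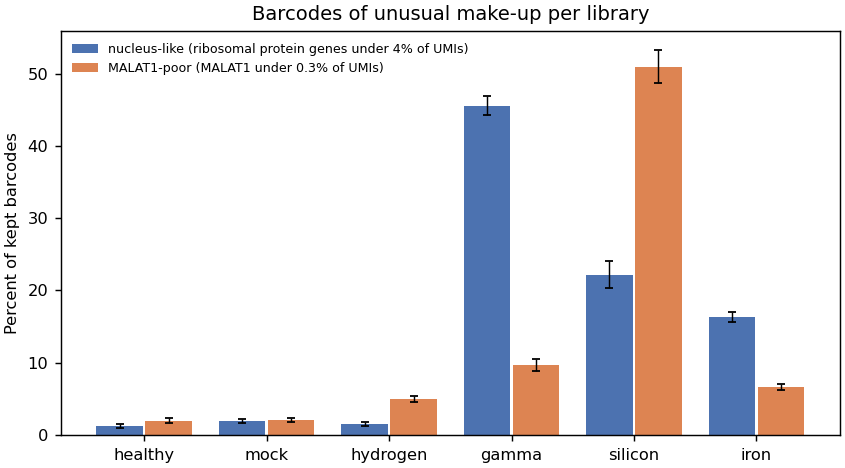
Percent of kept barcodes in each of the 6 libraries that were nucleus-like (ribosomal protein genes under 4% of UMIs) or MALAT1-poor (MALAT1 under 0.3% of UMIs), with exact 95% intervals for counting error. Nucleus-like barcodes reached 45.5% in gamma and MALAT1-poor barcodes 51.0% in silicon, while both stayed near 2% in the healthy and mock libraries.

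Mock against healthy shows how far the control for the irradiation lay from a low-passage culture. Mock had more transcripts of proliferating cells. MKI67, a marker of cycling cells, was at 102 CPM in mock and 40.2 CPM in healthy, 2.53-fold higher (interval 2.42 to 2.64), and TOP2A, which untangles chromosomes before mitosis, was 2.06-fold higher. All 28 G2/M genes detected were at least 1.5-fold higher in mock (median log2 ratio 1.24), among them BIRC5 (74.1 against 26.5 CPM), PTTG1, AURKB and CDKN3. Of 25 G1/S genes detected, 22 were higher and 0 lower (median 1.04), led by RRM2 (53.6 against 20.3 CPM), CLSPN, CCNE2 and TYMS. The lamina and chromatin list had 14 of 19 members higher (median 0.75), with the condensin genes NCAPH and NCAPG and the chromatin proteins HMGA1 and HMGA2 (109 against 48.6 CPM) at the top. DNA double-strand break repair genes had 10 of 26 higher and 0 lower (median 0.30). These medians all exceeded those of every random list of matched expression.

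Inflammatory transcripts and some matrix genes were lower in mock than in healthy. Of 14 cytokine and chemokine genes detected, 10 were at least 1.5-fold lower (median −1.06), including CXCL2 (14.3 against 63.0 CPM), CXCL3, IL6 (20.2 against 56.6 CPM, 2.80-fold lower) and CXCL1, while IL11 was higher (215 against 135 CPM). CXCL8 was 2.31-fold lower, CCL2 2.02-fold lower and IL1B 2.13-fold lower. Collagen genes had 6 of 28 members lower and 0 higher (median −0.27), with COL3A1 at 1232 CPM in mock and 2985 CPM in healthy. The largest single differences by the gene rule were SRGN, a proteoglycan core protein (28.8 against 5.65 CPM), PSG4, whose reads may be shared with near-identical family members (20.1 against 4.54 CPM), and DNER (21.2 against 5.78 CPM) on the higher side. On the lower side they included GCH1, the first enzyme of tetrahydrobiopterin synthesis (2.74 against 23.9 CPM), IGFBP2 (6.52 against 36.2 CPM) and TNFAIP3, an inhibitor of NF-κB signalling (32.8 against 162 CPM). Further genes named by the rule were ANKRD1, SLC35F3, E2F7, SPC25, PBK and SPOCK1, 2.74-fold to 3.604-fold higher, and PIEZO2, CXCL2, C11orf96, ARHGAP28, ADGRL2 and TMTC2, 3.99-fold to 4.77-fold lower.

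Further groups differed less evenly between the controls. The cyclin-dependent kinase inhibitors had 3 of 7 members lower in mock (median −0.34), with CDKN2A 1.74-fold lower and CDKN2B 1.72-fold lower, while CDKN1A was 1.33-fold higher. Myofibroblast genes had 2 of 17 higher (median 0.30), ACTA2 at 1277 against 869 CPM. Among proteases, MMP1 was 2.32-fold, MMP3 5.07-fold (interval 4.40 to 5.88) and MMP10 higher (5.01 against 0.945 CPM), with a list median of 0.04. Over all genes, 155 were at least 2-fold higher and 175 at least 2-fold lower in mock among 9088 compared. The control libraries differ in proliferation and in inflammatory transcripts, so the irradiated libraries are described against mock and then, more briefly, against healthy.

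All 4 irradiated libraries had far fewer transcripts of proliferating cells than mock. Of 28 G2/M genes, 27 were at least 1.5-fold lower in each of the 4 libraries. The exception was AURKA, at 45.4 CPM in mock and between 38.4 and 58.7 CPM in the irradiated libraries. The median log2 ratio was −2.92 in hydrogen, −3.04 in gamma, −4.29 in silicon and −3.40 in iron. CCNA2, the cyclin of S phase and G2, was at 62.3 CPM in mock and at 3.99, 4.45, 2.25 and 3.16 CPM in hydrogen, gamma, silicon and iron, and CDK1, KIF20A and TOP2A were next. MKI67 was 11.6-fold lower in hydrogen (interval 10.7 to 12.6), 9.84-fold in gamma (8.84 to 10.97), 22.2-fold in silicon (17.2 to 29.2) and 17.7-fold in iron (16.1 to 19.6). Of the G1/S genes, 24 of 25 were lower in hydrogen and in gamma, 24 of 26 in silicon and 23 of 25 in iron, with medians of −1.84, −1.84, −2.27 and −2.12. CLSPN, DTL, RRM2 and CDC45, which act in DNA replication, were the furthest below mock, and CCNE1 was at least 1.5-fold higher in silicon (log2 ratio 0.72).

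Genes of the nuclear lamina and chromatin followed. In each irradiated library 16 of 19 members were at least 1.5-fold lower than in mock, with medians of −1.51 in hydrogen, −1.66 in gamma, −1.76 in silicon and −1.80 in iron. LMNB1 (ENSG00000113368, chromosome 5, 126776623 to 126837020), which encodes lamin B1 and is used as a marker of senescence when low, was at 21.5 CPM in mock and 13.8 CPM in healthy. It was 10.4-fold lower than mock in hydrogen (interval 8.77 to 12.4), 8.14-fold in gamma (6.58 to 10.2), 11.6-fold in silicon (7.75 to 18.1) and 14.9-fold in iron (12.3 to 18.3). HMGB2, a chromatin protein, was 4.96-fold, 5.59-fold, 10.6-fold and 5.41-fold lower, and NCAPG and NCAPH were the furthest below mock. HMGA2, a chromatin protein found in senescent cells, went the other way, at 109 CPM in mock and 563, 942, 713 and 553 CPM in hydrogen, gamma, silicon and iron. Of 26 double-strand break repair genes, 17 were lower in hydrogen, gamma and silicon and 16 in iron (medians −0.96, −0.67, −0.90 and −0.95). RAD51AP1, FANCD2, BRCA2 and BLM, which act in homologous recombination, were the lowest. ATR, a damage-signalling kinase, and ATM were higher in gamma at 59.8 and 92.2 CPM, against 28.5 and 50.1 CPM in mock. XRCC4, an end-joining factor, was higher in silicon and iron at 88.4 and 67.8 CPM against 35.4 CPM. In the remaining cells 0 of 26 repair genes were at least 1.5-fold higher in gamma or in iron, so ATR and ATM in gamma and XRCC4 in iron did not stay so. For the G1/S, G2/M, lamina and repair lists, every median lay below those of all random lists. The G2/M median over the remaining cells was −2.54 in gamma and −3.37 in silicon. Log2 ratios over mock in these cells were −2.69 for MKI67 in gamma (−3.298 in all cells) and −3.32 in silicon (−4.47), and for TOP2A −2.76 in gamma (−3.35) and −4.02 in silicon (−4.83). In silicon LMNB1 was at −2.43 (−3.53) and HMGB2 at −2.63 (−3.41).

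**Figure D2:**
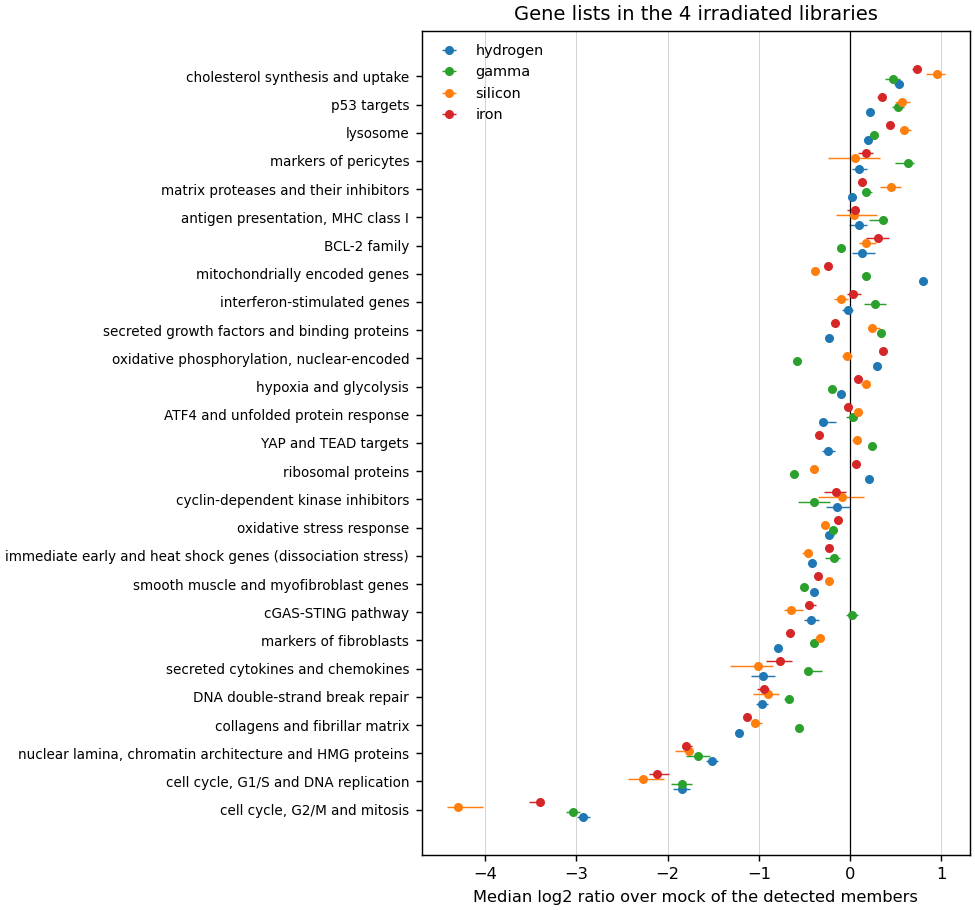
Median log2 ratio over mock of the detected members of each gene list (at least 5 detected members) in the hydrogen, gamma, silicon and iron libraries, with lines for 95% intervals of counting error. The G2/M medians lie between −2.92 and −4.29 and the G1/S medians between −1.84 and −2.27, while cholesterol synthesis lies between 0.47 and 0.95; medians near 0 in gamma and silicon can change sign with the scaling.

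The share of cells with these transcripts was lower too. After thinning to 3000 UMIs, 35.9% of mock cells (interval 34.9 to 36.9) and 12.7% of healthy cells had UMIs of 3 or more G2/M genes. The share was 3.97% in hydrogen (3.54 to 4.43), 4.40% in gamma (3.79 to 5.08), 1.28% in silicon (0.746 to 2.04) and 2.40% in iron (2.02 to 2.84). Cells outside the cluster of cycling-like cells, where the signal may come from free RNA, gave 9.77% in mock, 3.80% in hydrogen, 2.97% in gamma, 1.05% in silicon and 2.14% in iron. All 4 irradiated shares lie under the 9.77% found in those mock cells. Free RNA depends on each library's own cells, so the mock share does not measure the background in the irradiated libraries. Whether the irradiated shares come from cycling cells or from background was therefore left open. MKI67 was found in 17.7% of mock cells and in 0.601% to 1.87% of irradiated cells, and LMNB1 in 6.06% of mock cells and in 0.265% to 0.787% of irradiated cells. CDKN1A was found in 55.9% of mock cells and in 71.1% of hydrogen, 57.4% of gamma, 71.8% of silicon and 76.4% of iron cells, and among the remaining cells of gamma and silicon the shares were 78.3% and 90.0%. CDKN2A was found in 6.58% of mock and 10.8% of healthy cells, against 25.8% of hydrogen, 13.6% of gamma, 23.8% of silicon and 28.3% of iron cells. No cell type in these libraries should lack CDKN1A, CDKN2A or LMNB1, so the background from free RNA was not measured for them. The thinned shares rest on 7164 healthy, 8981 mock, 7666 hydrogen, 4066 gamma, 1331 silicon and 5660 iron cells.

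**Figure D3:**
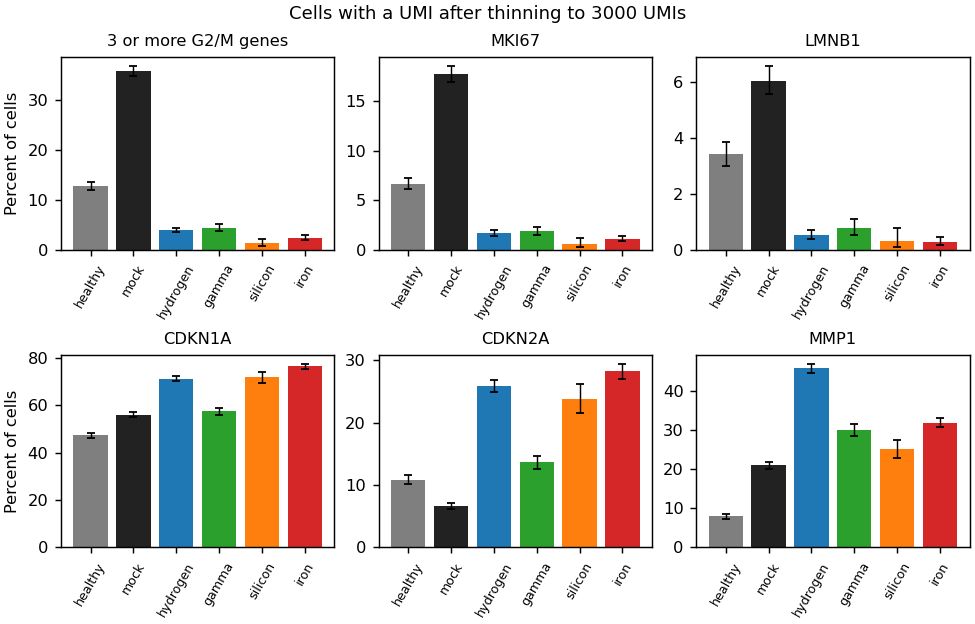
Percent of cells with UMIs of 3 or more G2/M genes, or with at least 1 UMI of MKI67, LMNB1, CDKN1A, CDKN2A or MMP1, per library after thinning each cell to 3000 UMIs; bars carry exact 95% intervals for counting error. G2/M cells made up 35.9% of mock and 1.28% to 4.40% of the irradiated libraries, and CDKN2A was found in 6.58% of mock cells and 13.6% to 28.3% of irradiated cells.

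Inhibitors of cyclin-dependent kinases went in both directions. Of 7 members, 1 to 3 were higher and 3 lower than mock in each irradiated library, with medians of −0.14 in hydrogen, −0.39 in gamma, −0.09 in silicon and −0.16 in iron. Over the remaining cells the median was 0.25 in silicon and 0.01 in iron, and 1 member was lower in gamma. CDKN2A, whose products p16 and p14ARF restrain the cell cycle, was 4.08-fold higher in hydrogen (interval 3.91 to 4.27), 2.25-fold in gamma (2.12 to 2.39), 4.49-fold in silicon (4.21 to 4.79) and 4.53-fold in iron (4.34 to 4.73). CDKN1A, which encodes p21, was at 469 CPM in mock and at 531, 572, 896 and 622 CPM, a difference of 1.13-fold to 1.91-fold. CDKN2B was 1.38-fold, 1.47-fold, 3.09-fold and 1.94-fold higher than mock. Mock lay further below healthy than hydrogen and gamma lay above mock, so CDKN2B was lower in hydrogen and gamma than in healthy. CDKN2C and CDKN1B were lower, with CDKN2C at 11.3 CPM in mock and 1.62 to 2.16 CPM after irradiation. Of 29 p53 targets, 3 were higher and 0 lower in hydrogen, 13 and 3 in gamma, 14 and 2 in silicon, and 6 and 0 in iron. Their medians were 0.22, 0.53, 0.57 and 0.35, above at least 99.72% of random lists. In mock over healthy the median was 0.24, above 99.96% of random lists, with 0 members higher and 3 lower. Such a percentile is therefore not particular to the irradiated libraries. FUCA1, a lysosomal fucosidase, BTG2, GDF15 and SESN2 led this list. GDF15, a secreted stress signal, was 3.70-fold higher in hydrogen (3.51 to 3.90), 2.53-fold in gamma (2.37 to 2.71), 5.49-fold in silicon (5.11 to 5.90) and 5.27-fold in iron (5.01 to 5.54). MDM2, the ubiquitin ligase of p53, was 1.40-fold, 2.84-fold, 1.76-fold and 1.59-fold higher. Among the remaining cells the log2 ratio of GDF15 in silicon was 3.09 (2.46 in all cells) and that of MDM2 in gamma 0.92 (1.504). BAX and TRIAP1 were lower in gamma and silicon, and TP53I3 in gamma. In the remaining cells, however, 15 of 29 targets were higher and 1 lower in gamma (median 0.61). In those of silicon 20 of 29 were higher and 0 lower (median 0.87). Of 9 BCL-2 family genes, 2 or 3 were higher and 1 lower in each library (medians 0.13 in hydrogen, −0.10 in gamma, 0.17 in silicon and 0.30 in iron, with silicon turning negative under the TMM and median-of-ratios scalings and gamma at 0.21 in the remaining cells). BCL2L1, which encodes the survival protein BCL-xL, was at 23.7 CPM in mock and at 57.5, 58.8, 100.4 and 60.1 CPM in hydrogen, gamma, silicon and iron.

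**Figure D4:**
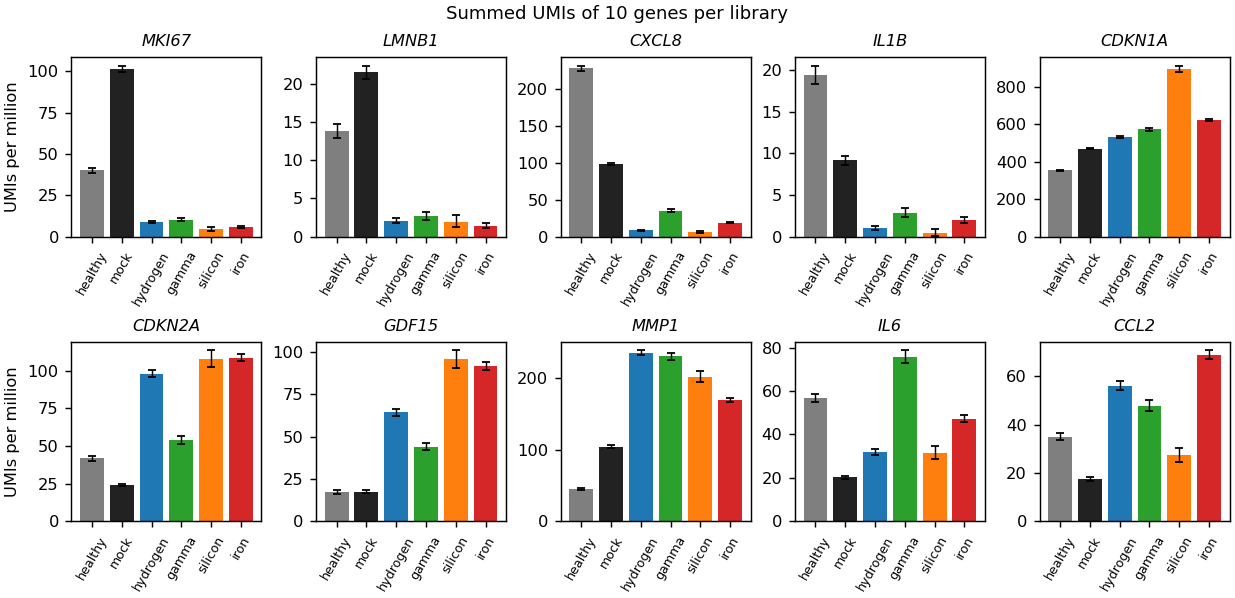
CPM of MKI67, LMNB1, CXCL8, IL1B, CDKN1A, CDKN2A, GDF15, MMP1, IL6 and CCL2 in the 6 libraries, with 95% Poisson intervals for counting error. LMNB1 lies between 1.44 and 2.64 CPM in the irradiated libraries against 21.5 in mock, and CXCL8 between 6.51 and 35.1 CPM against 98.7 in mock and 228 in healthy.

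Secreted cytokines and chemokines went in both directions. Of 15 detected, 3 were higher and 8 lower in hydrogen, 5 and 6 in gamma, 4 and 9 in silicon, and 5 and 9 in iron, with medians of −0.95, −0.46, −1.003 and −0.77. Over the remaining cells of gamma the median was 0.05. CXCL8, a neutrophil chemokine, was 11.7-fold lower than mock in hydrogen (interval 10.8 to 12.7), 2.81-fold in gamma (2.65 to 2.99), 15.2-fold in silicon (12.2 to 19.0) and 5.26-fold in iron (4.98 to 5.57). CXCL1 was at 27.5 CPM in mock and under 1 CPM in every irradiated library, and CXCL6 was at 7.32 CPM in mock and had 0 counts in silicon and iron. IL1B was 8.85-fold, 3.21-fold, 23.6-fold and 4.69-fold lower, the silicon value resting on 5 counts (interval 10.1 to 72.9). In silicon the log2 ratios over the remaining cells were −3.32 for CXCL8 (−3.92 in all cells) and −3.87 for IL1B (−4.56). IL6 was higher than mock in all 4, by 1.58-fold in hydrogen (1.49 to 1.68), 3.75-fold in gamma (3.55 to 3.97), 1.56-fold in silicon (1.40 to 1.73) and 2.33-fold in iron (2.21 to 2.46). With cells carrying cell-cycle UMIs left out, IL6 was lower than mock in hydrogen (log2 ratio −0.17) and silicon (−0.58). Against healthy, at 56.6 CPM, only gamma was higher, at 75.8 CPM. CCL2, a monocyte chemokine, was 3.24-fold, 2.75-fold, 1.58-fold and 3.97-fold higher than mock, but in silicon it was lower than in healthy. IL32 was at 3.07 CPM in mock and 48.6, 49.2, 26.3 and 58.0 CPM after irradiation. The immediate early genes FOS, FOSB and EGR1, which handling can induce, were also lower in the 4 irradiated libraries than in mock.

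Growth factors and proteases were mixed as well. Of 25 growth factor and binding protein genes, 7 were higher and 9 lower in hydrogen, 6 and 9 in gamma, 8 and 8 in silicon, and 9 and 8 in iron. The medians were −0.23, 0.34, 0.25 and −0.17, and silicon turned negative under TMM. Gamma was at −0.18 with 5 lower in the remaining cells, and silicon had 13 higher there. IGFBP2, which binds insulin-like growth factors, was at 6.52 CPM in mock and 36.2 CPM in healthy, and at 305, 156, 296 and 363 CPM in hydrogen, gamma, silicon and iron. AREG, HGF and EREG, which encode secreted growth factors, were lower in all 4, with AREG at 229 CPM in mock and 14.1 to 17.6 CPM after irradiation. IGFBP3 was 2.13-fold higher than mock in silicon (2.10 to 2.16) and lower in hydrogen by 1.86-fold (1.84 to 1.89), in gamma by 1.68-fold and in iron by 1.12-fold. Of the protease list, 3 of 18 were higher and 5 lower in hydrogen, 4 and 4 of 19 in gamma, 8 and 5 of 19 in silicon, and 7 and 6 of 18 in iron. Its medians were 0.02, 0.17, 0.45 and 0.13, and gamma turned negative under both other scalings. MMP1, an interstitial collagenase, was at 104 CPM in mock and 235, 230, 202 and 170 CPM in the 4 libraries, and PLAT, a plasminogen activator, was at 58.2 CPM in mock and 136 to 174 CPM. MMP3 was lower by 8.49-fold, 7.81-fold, 3.99-fold and 4.90-fold, and MMP10 and ADAMTS5 were lower too.

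Matrix genes were lower. Of 28 collagen and fibrillar matrix genes, 20 were at least 1.5-fold lower in hydrogen, 13 in gamma, 18 in silicon and 17 in iron, and 3 or 4 were higher. The medians were −1.21, −0.56, −1.04 and −1.13, and the highest of their percentiles among random lists was 0.38, in gamma. COL3A1 was at 1232 CPM in mock and 170, 281, 276 and 223 CPM after irradiation, and TNC and COL12A1 were lower as well. COL11A1, the collagen crosslinking enzyme LOX and fibronectin (FN1) were higher, with FN1 at 2879 CPM in mock and 5102, 8073, 8391 and 6383 CPM. COL1A1 was 1.87-fold lower in hydrogen, 1.46-fold in gamma and 1.42-fold in iron and differed by 1.02-fold in silicon, a difference that changed direction with the scaling. Of 17 myofibroblast genes, 6 were lower in hydrogen, silicon and iron and 8 in gamma, with medians of −0.40, −0.51, −0.23 and −0.36. In each library 1 or 2 were higher, and the medians lay above 1.36% (hydrogen) to 12.6% (silicon) of random lists. Against healthy the medians were −0.09, −0.22, −0.02 and 0.06. ACTA2, smooth muscle actin, was 2.87-fold, 4.18-fold, 3.48-fold and 2.94-fold lower than mock, and MYH11, TGFB1 and TPM1 were lower. The myofibroblast median was −0.15 in gamma (5 lower) and −0.14 in silicon in the remaining cells, and the collagen median −0.39 and −0.82.

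Genes of cholesterol synthesis were higher, and lysosomal genes less evenly so. Of the cholesterol genes, 8 of 18 were higher and 1 lower in hydrogen, 9 and 0 of 18 in gamma, 16 and 0 of 19 in silicon, and 13 and 1 of 18 in iron. The medians were 0.53, 0.47, 0.95 and 0.73, above at least 98.7% of random lists. MSMO1 and DHCR7, late enzymes of cholesterol synthesis, and SREBF2, which encodes a transcription factor of this pathway, were among the leading members. MSMO1 was at 17.1 CPM in mock and 44.5, 33.6, 69.9 and 53.2 CPM in the 4 libraries. Of 22 lysosomal genes, 7 were higher in hydrogen, 4 in gamma, 11 in silicon and 7 in iron, and 2 lower in each (medians 0.20, 0.27, 0.59 and 0.44). These lay above 98.8% of random lists in hydrogen, 89.2% in gamma, 99.97% in silicon and 99.98% in iron, so gamma was inside the range of random lists, although 11 of 22 were higher (median 0.56) in its remaining cells. PSAP, a precursor of sphingolipid activators, was at 154 CPM in mock and 236 to 406 CPM, while NPC1 and GUSB were lower. Both lists kept their sign under the other scalings.

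Mitochondrial and ribosomal genes differed between the radiations. Of 24 nuclear-encoded genes of oxidative phosphorylation, 12 were lower in gamma (median −0.58), 2 were higher in hydrogen (0.29), 5 in iron (0.36), and 1 was higher and 1 lower in silicon (−0.04). Over the remaining cells gamma was at −0.12 with 0 lower, silicon at 0.04, and iron had 9 higher. NDUFB2, a subunit of complex I, was at 219 CPM in mock and 437, 187, 433 and 452 CPM. The mitochondrially encoded genes had 9 of 13 members higher in hydrogen (median 0.80), where the median mitochondrial share of UMIs was 4.94% against 2.56% in mock. They had 0 higher and 0 lower in gamma (0.18, turning negative under both other scalings and in the remaining cells), 4 lower in silicon (−0.38, with 7 lower in the remaining cells) and 3 lower in iron (−0.24). MT-ND1 was at 960 CPM in mock, 2125 CPM in hydrogen and 1047 to 1176 CPM in the other irradiated libraries. Of 24 ribosomal protein genes, 14 were lower in gamma (−0.62) and 9 in silicon (−0.40), with medians of 0.21 in hydrogen and 0.07 in iron. These were −0.07 in gamma, with 0 lower, and −0.27 in silicon in the remaining cells, which were chosen by their ribosomal protein UMIs, so that this change follows in part from the choice. Oxidative stress genes had 6 of 20 lower in hydrogen and gamma, 8 in silicon and 7 in iron (medians −0.23, −0.19, −0.27 and −0.14, with gamma at 0.07 and 2 lower in the remaining cells). In the same order 3, 3, 0 and 4 were higher, and iron had 6 higher and 6 lower in the remaining cells. These medians lay above 3.37% (silicon) to 27.9% (iron) of random lists, inside their range. NQO1, a quinone reductase, was at 209 CPM in mock and 63.3, 50.4, 32.3 and 64.6 CPM, and the pentose phosphate enzymes TKT and PGD were also lower.

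Counted over all genes against mock, hydrogen had 446 at least 2-fold higher and 777 lower of 9253 compared, gamma 1244 and 675 of 9629, silicon 1003 and 817 of 9597, and iron 563 and 840 of 9327. The balance in gamma and silicon depended on scaling. TMM moved the median of all genes by −0.23 in gamma and −0.27 in silicon and gave 876 higher and 1177 lower genes in gamma, and 633 and 1324 in silicon. Median-of-ratios scaling gave 806 and 1097 in gamma and 600 and 1162 in silicon, with shifts of −0.23 and −0.25. In the remaining cells the counts were 514 and 456 in gamma, 895 and 722 in silicon, 498 and 1072 in iron (shift −0.10) and 428 and 826 in hydrogen. Without nucleus-like barcodes alone they were 475 and 469 in gamma, 665 and 1179 in silicon and 475 and 1103 in iron. With cells weighted equally silicon had 744 and 1201 (shift −0.19) and iron 818 and 812. With cells carrying cell-cycle UMIs left out, iron had 815 and 718 (shift 0.15), and mock against healthy had 50 and 124. Against healthy, the counts were 527 and 927 in hydrogen, 1093 and 551 in gamma, 1019 and 871 in silicon, and 630 and 1008 in iron.

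Against healthy, which has fewer transcripts of proliferating cells than mock, several list medians were different. The G2/M medians were −1.76 in hydrogen, −1.74 in gamma, −3.06 in silicon and −2.19 in iron, with 25 of 27 genes lower in each (silicon at −2.09 in the remaining cells), and the G1/S medians −0.87, −0.88, −1.34 and −1.04. Lamina and chromatin genes were at −0.93, −0.87, −1.22 and −1.12. Of 22 repair genes, 12 were lower in hydrogen, 5 in gamma, 9 in silicon and 11 in iron (medians −0.604, −0.35, −0.56 and −0.59), and 3 were higher in gamma (0 in its remaining cells). Of the cholesterol genes, 5 of 18 were higher in hydrogen and in gamma, 13 of 19 in silicon and 6 of 18 in iron, with medians of 0.21, 0.26, 0.72 and 0.45, the gamma median above 90.5% of random lists. Cytokine medians were −1.85 in hydrogen, −0.29 in gamma, −1.83 in silicon and −1.35 in iron, further below 0 than over mock in all but gamma. In its remaining cells gamma was no exception, at −0.73 against healthy and 0.05 over mock. Medians on the other side of 0 were 0.34 in silicon and 0.18 in iron for the cyclin-dependent kinase inhibitors, −0.13 in gamma and −0.04 in silicon (0.198 in its remaining cells) for growth factors, −0.17 in hydrogen for proteases, 0.06 in iron (−0.12 in its remaining cells) for myofibroblast genes and 0.08 in silicon for nuclear-encoded oxidative phosphorylation.

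Genes that set all 4 irradiated libraries apart from both controls were asked for next. Of 10041 genes, 322 were at least 2-fold higher and 258 at least 2-fold lower than both mock and healthy in every irradiated library. Independent libraries would share 0.187 and 0.129 genes, and 20 simulations with counting error alone gave 0 at most. All 4 libraries are set against the same controls, so part of this excess may come from those shared controls. The simulations held no spread between cultures, so their 0 does not show how many genes unirradiated cultures would share. In the remaining cells the counts were 223 and 247, of which 198 and 187 were in both sets. The highest was TMEM178B (ENSG00000261115, chromosome 7, 141074064 to 141480380), a transmembrane protein gene, at 1.68 CPM in mock and 0.583 CPM in healthy, and at 76.2, 159, 235 and 151 CPM in hydrogen, gamma, silicon and iron. It was followed by CLSTN2, NFASC, DYNC1I1, HDAC9, SERPINB7, CLDN1, MAP3K7CL, NTNG1 and CPA4, whose smallest ratios ran from 11.7-fold to 43.4-fold. Over the remaining cells the smallest log2 ratio was 4.88 for TMEM178B (5.501 in all cells), under the 5.47 of CLSTN2, and it was 4.12 for NFASC (5.13) and 3.69 for DYNC1I1 (4.75). HDAC9, a histone deacetylase, was at 5.44 CPM in mock and 127 to 202 CPM after irradiation, and CLDN1, a tight junction protein, at 2.84 CPM and 41.6 to 85.3 CPM. The lowest was CXCL1 (ENSG00000163739, chromosome 4, 73869393 to 73871308), at 27.5 CPM in mock, 74.6 CPM in healthy and at most 0.989 CPM in the irradiated libraries, where silicon had 1 count. TSPAN12, TNFAIP6, ACTC1, AREG, COL14A1, SAMD11, GRIA4 and HSPA2 were among those that followed, 7.51-fold to 19.8-fold lower at the nearest ratio. The log2 ratio of ACTC1 nearest to 0 was −2.999 in the remaining cells (−3.805 in all cells). TNFAIP6, a hyaluronan-binding protein, was at 20.8 CPM in mock and 0.918 to 1.37 CPM after irradiation.

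By list, the shared lower genes held 23 of 28 G2/M genes, 5 of 17 G1/S genes (MCM3, MCM7, RRM2, CLSPN and DTL) and 8 of 19 lamina and chromatin genes (LMNB1, HMGB1, HMGB2, HMGB3, EZH2, SMC4, NCAPG and NCAPH). They also held 6 of 15 cytokines (CXCL8, CXCL1, CXCL6, CXCL12, IL1B and IL11), 8 of 28 matrix genes (COL3A1, COL5A2, COL4A1, COL4A2, FBLN5, DCN, POSTN and TNC) and the growth factors HGF, EREG, AREG and ANGPT1, with BRCA2, CDKN2C, ADAMTS5, MYH11, TGFB1, NQO1, EGR2 and S100A4 among others. The shared higher genes held HMGA2, IL32, IGFBP2, GDF15, HBEGF, COL11A1, LOX, PLAT and BCL2L1. GDF15 was the only p53 target among them, and CDKN1A and CDKN2A were not, since at least 1 of their 8 ratios was under 2-fold.

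Each radiation was then compared with the nearest of the other 3, over 7116 genes. Hydrogen had 0 genes at least 2-fold above or below all others. LRRC75A was at 95.2 CPM in hydrogen and 50.4 CPM in iron, the next highest, and C1orf56 was 1.89-fold above iron. MTRNR2L12, HIST1H4C and PTTG1 were 1.36-fold to 1.40-fold above, and reads of MTRNR2L12 and of the histone gene HIST1H4C can be shared with near-identical copies. CYP1B1, a cytochrome P450, was at 7.82 CPM in hydrogen and 15.3 CPM in iron, and KCTD16, SETBP1, CLSTN2 and TMEM178B were 1.79-fold to 1.98-fold below the others. TMEM178B lay above the nearest library instead in the remaining cells (log2 gap 0.61 in place of −0.99), and the gaps of KCTD16 and SETBP1 shrank to −0.11 and −0.18.

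Gamma stood furthest from the other radiations by these counts, with 218 genes at least 2-fold above and 36 at least 2-fold below. For each radiation against the others, such counts were made with scaling to total UMIs only. Other scalings moved the counts of gamma and silicon over mock, so these counts may depend on scaling too. CEMIP (ENSG00000103888, chromosome 15, 80779343 to 80951776), which takes part in hyaluronan breakdown, was at 953 CPM in gamma and at 169, 114 and 179.5 CPM in hydrogen, silicon and iron. DPF3, C7orf69, TGFBR3 and ABI3BP were next, 3.64-fold to 3.95-fold above the nearest. COX7A1, a subunit of cytochrome c oxidase (17.7 against 58.1 CPM in hydrogen), ANKRD1 (59.8 against 179 CPM), the metallothionein MT1X, TMEM208 and C5orf46 were the furthest below. The log2 gap of CEMIP over the remaining cells was 1.40 in place of 2.41, that of DPF3 0.97 in place of 1.98, that of C7orf69 0.94 in place of 1.93 and that of TGFBR3 1.14 in place of 1.89, and 32 of the 218 genes stayed at least 2-fold above.

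Silicon had 3 genes at least 2-fold above the others, among them IGFBP3 (1948 against 817 CPM in iron) and the clock gene ARNTL, with COL11A1 and the protease inhibitor TIMP3 next. The 16 genes at least 2-fold below included C1R, a serine protease of the complement system (3.02 CPM in silicon, 16.0 CPM in hydrogen), the pentraxin PTX3, PCOLCE, which enhances procollagen processing, and the heparin-binding growth factors MDK and PTN. PTN was at 26.6 CPM in silicon and 101 CPM in iron. Iron had 2 genes at least 2-fold above the others, HIST2H2AA4 (27.8 against 7.82 CPM in silicon), whose near-identical copy makes its reads uncertain, and FKBP2 (24.8 against 12.2 CPM). ARF5, OOEP and SYVN1 were 1.36-fold to 1.75-fold above. Iron had 0 genes 2-fold below, and DACH2, MMP16, ANO4, DOT1L and BDNF-AS (ENSG00000245573) were the furthest below, 1.41-fold to 1.58-fold. The gap of ANO4 was −0.05 in the remaining cells and that of BDNF-AS turned to 0.23.

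Silicon and iron, with high linear energy transfer, were compared with gamma and hydrogen. Both lay above the other pair for 1297 genes and below it for 687 of 9540, together 20.8%, under the 33.3% that chance gives. Of these, 11 were at least 2-fold above and 7 at least 2-fold below (5 and 8 in the remaining cells). The other pairings separated 71.4% of genes (silicon and gamma against iron and hydrogen, with 1 gene at least 2-fold above and 5 below) and 7.83% (silicon and hydrogen against iron and gamma, with 0 and 3). A gene can be separated by only 1 of these pairings, so a large share for any pairing lowers the others. The 33.3% also takes every order of the libraries as equally likely. These shares count order at any size and depend on scaling. They were 28.7%, 60.1% and 11.2% under TMM, 27.998%, 61.0% and 10.97% under median-of-ratios scaling, and 24.9%, 61.9% and 13.2% in the remaining cells. At 2-fold the pairing by linear energy transfer held the most genes in all cells, whereas TMM gave it 11 and 8 genes against 0 and 48 for silicon and gamma, so which pairing stands out depends on the measure. The genes furthest above were DYNC1I1, a dynein subunit (24.3 CPM in silicon and 18.5 CPM in iron, 7.66 CPM in gamma and 7.56 CPM in hydrogen), ZPLD1, CSMD2 and KISS1, followed by MANCR, RIMS1, the protease inhibitor SERPINE2, AMIGO2, C5orf46 and NFASC. The gap of RIMS1 was 0.17 in the remaining cells, against 0.80 in all cells. Among the genes furthest below were NLGN1, a synaptic adhesion protein (28.1 and 30.3 CPM against 149.9 CPM in gamma and 79.6 CPM in hydrogen), EML5 and the secreted glycoprotein RELN. STX17-AS1 (ENSG00000255145), LDB2, HGF, ANKRD33B, NPTX1 and SLIT2 followed, and the gap of NPTX1 was −0.01 in the remaining cells.

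Joint clustering of all cells gave 10 clusters at resolution 0.5. Only cluster 7 could be named by the marker sets, as cycling-like cells. With 1 library per group, a cluster made mostly of 1 library may be that library, so cluster sizes were not compared between groups.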

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

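The tests of barcode make-up and of depth for the gamma library, and the test of CXCL8 alone, were chosen after the results were seen; the other tests were written beforehand.

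IGFBP3 (ENSG00000146674, chromosome 7, 45912245 to 45921874), which binds insulin-like growth factors, lay on opposite sides of mock in different irradiated libraries. Its log2 ratio over mock was 1.09 in silicon and −0.90 in hydrogen, a difference of 1.99, and it was −0.75 in gamma and −0.17 in iron. What drew attention was that both ratios passed 1.5-fold in opposite directions. The difference was not tested, since each group has 1 library. The silicon ratio stayed between 0.84 and 1.33 and the hydrogen ratio between −0.98 and −0.84 under all alternatives run. No technical or biological explanation was tested for it.

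In the gamma library 218 genes were at least 2-fold above all other irradiated libraries, and thinning every cell to 3000 UMIs left 211 of them so (96.8%). Random thinning keeps the expected proportions of genes in each cell, so this result cannot decide on lower depth per cell as a cause. A filter of 2000 genes and 10% mitochondrial UMIs left 95 (43.6%), but 216 when it spared nucleus-like and MALAT1-poor barcodes, which were 81.8% of the gamma barcodes it took out. Without nucleus-like and MALAT1-poor barcodes 32 stayed (14.7%), without nucleus-like barcodes alone 40 (18.3%), and in the former the median log2 gap went from 1.18 to 0.63, while leaving out as many barcodes at random left 196 (89.9%). These genes were higher in nucleus-like than in other gamma barcodes, with a median log2 ratio of 1.55, against −0.05 over all 7116 genes compared. Most of this pattern may therefore come from the 45.5% of gamma barcodes called nucleus-like. What these barcodes are, and whether gamma rays or sample handling gave them, was not tested.

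CXCL1, CXCL8 and IL1B were lower in all 4 irradiated libraries than in both controls. Leaving out nucleus-like and MALAT1-poor barcodes kept the largest of the 24 log2 ratios at −1.17 (−1.49 in all cells), which argues against barcode make-up. For handling stress, thinned cells with no UMI of 6 immediate early genes were compared, which made up 0.796% of healthy and 2.55% of mock cells against 13.7% to 30.3% of irradiated cells. There the largest ratio was −0.23, from 0 CXCL1 counts in silicon against 2 in mock, which are too few to decide for the set. For CXCL8 alone the largest was −1.47 (interval −2.43 to −0.51), from 21 counts in gamma and 20 in mock. CXCL8 thus stayed lower in these cells, but having no UMI of the 6 genes does not show that a cell escaped handling stress. Handling as a cause for CXCL1, CXCL8 and IL1B and irradiation itself stay open, the latter untested with 1 library per group.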

How the results depend on the processing

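The alternatives without nucleus-like or MALAT1-poor barcodes, without the gamma library and without the silicon library, and other scalings for the pairings of irradiated libraries, were chosen after seeing the data; all others were planned. No paired analysis was possible because each group has 1 library, and no replicate could be left out. Of 168 values of 2-fold counts over 12 results, 144 stayed within 1.5 times and 24 moved. Of 1592 list medians 838 stayed within counting error, 745 moved and 9 changed sign from at least 1.5-fold. Of 1045 ratios of genes chosen in advance 611 stayed, 427 moved and 7 changed sign from at least 1.5-fold, and of 1100 gaps of ranked genes 903 stayed, 194 moved and 3 did so. With values nearer to 0 included, 137 list medians, 19 ratios and 15 gaps changed sign. Of 240 shares of cells 56 stayed and 184 moved, and of 18 shares in the cycling cluster 13 stayed and 5 moved, and a share has no sign. Depth limits silicon most, where 3 counts equal 0.232 CPM.

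A floor of 50 CPM compares fewer genes and so gave fewer 2-fold genes, with 170 higher and 328 lower in hydrogen than mock, 561 and 282 in gamma, 398 and 336 in silicon, 224 and 358 in iron, 46 and 61 in mock against healthy, and 114 and 106 shared by all 4. Gamma higher genes numbered 806 under median-of-ratios, 514 without nucleus-like and MALAT1-poor barcodes and 475 without nucleus-like barcodes, and lower genes 1177 under TMM and 1097 under median-of-ratios. Silicon higher genes numbered 633 under TMM, 600 under median-of-ratios and 665 without nucleus-like barcodes, and lower genes 1324 under TMM. For these the cause was not tested. Genes shared as higher numbered 198 without nucleus-like barcodes, and genes shared as lower 452 without the gamma library, which asks for 3 libraries in place of 4. Leaving out silicon also asks for 3, and it kept the shared lower count within 1.5 times. Gamma had the fewest genes at least 2-fold lower than both controls, 419 against 633 in hydrogen, 682 in silicon and 722 in iron.

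Leaving out cells with 2 or more UMIs of the cell-cycle lists selects cells on those lists' own genes and removes more cells where depth is greater (1182 of 9404 mock cells stayed), so by construction it lowers these genes most in mock. Under it the G1/S median was 0.11 in gamma and 0.40 in iron over mock and −0.62 in mock over healthy, and the G2/M median 1.58 in hydrogen, 1.65 in gamma, 1.35 in silicon and 2.13 in iron, with no member left to compare in mock over healthy. MKI67 and TOP2A were at 0.65 and 0.93 in hydrogen over mock. In mock over healthy TOP2A was at −0.44, LMNB1 at −0.79 and HMGB2 at −0.33. IL6 over mock was at −0.17 in hydrogen and −0.58 in silicon and the pericyte median in gamma at −0.089, and for these the cause was not tested. The pericyte median in gamma was −0.13 with healthy as the control. TMEM178B in hydrogen lay above the nearest library by 0.61 without nucleus-like and MALAT1-poor barcodes and by 0.59 without nucleus-like barcodes. DACH2 in iron lay at 0.027 with cells weighted equally. The cause was not tested for these 3 either.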

Other observations

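The test for damaged fibroblasts in cluster 10 was chosen after the results were seen; the other test was written beforehand.

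Groups tied to innate immunity had members in both directions. Of the interferon-stimulated genes, 2 of 8 detected were higher and 0 lower in hydrogen, 3 and 1 in gamma, 2 and 2 in silicon, and 2 and 0 of 9 in iron (medians −0.02, 0.27, −0.10 and 0.04, with hydrogen at 0.01 in the remaining cells), against −0.26 in mock over healthy. ISG15, a ubiquitin-like protein, was at 56.3 CPM in mock and 110.5, 44.7, 91.2 and 105 CPM in hydrogen, gamma, silicon and iron, with IFI6 higher in hydrogen, silicon and iron. Of 6 cGAS-STING genes, 3 were lower in hydrogen, silicon and iron and 1 in gamma (medians −0.42, 0.02, −0.65 and −0.45, gamma turning negative under both other scalings and in the remaining cells, at −0.13; 0.03 in mock over healthy). CGAS, the cytosolic DNA sensor, was at 5.98 CPM in mock and 1.39 to 2.76 CPM after irradiation, while TMEM173, which encodes STING, was at 9.18 CPM and 13.2 to 15.5 CPM. MHC class I genes had medians of 0.10, 0.36, 0.04 and 0.05 over 11 members (silicon turning negative under both other scalings) and −0.07 in mock over healthy. HLA-E was at 70.2 CPM in mock and 91.1 to 117 CPM, a count that reads shared among HLA genes make uncertain, and PSMB8 was at 15.5 CPM in mock and 4.42 CPM in silicon.

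Signalling and stress groups went different ways. YAP and TEAD targets had medians of −0.24 in hydrogen, 0.24 in gamma, 0.07 in silicon (negative under both other scalings) and −0.34 in iron over 14 members, and −0.11 in mock over healthy. ANKRD1 was at 38.04 CPM in mock and 179, 59.8, 329.9 and 207 CPM, and CCN1 was lower in all 4. The ATF4 and unfolded protein response medians were −0.30, 0.03, 0.09 and −0.02 over 21 members, gamma and silicon turning negative under both other scalings and iron at 0.05 in the remaining cells, and −0.09 in mock over healthy. The chaperone-like PDIA4 and the glutathione-degrading enzyme CHAC1 were lower in all 4 and the kinase-like TRIB3 higher. Hypoxia and glycolysis medians were −0.10, −0.20 (gamma, 0.23 in the remaining cells), 0.17 (silicon, negative under both other scalings) and 0.08 over 20 members and 0.03 in mock over healthy, with the glycolytic PFKP at 331 CPM in mock and 126 to 155 CPM and the carbonic anhydrase CA12 at 6.83 CPM and 9.92 to 30.9 CPM. Of 8 metallothioneins 3 were detected, with medians of 0.31, −1.05, 0.09 (silicon, negative under both other scalings) and 0.27 and 1.01 in mock over healthy, and MT1X was at 235 CPM in mock and 74.0, 30.04, 116 and 93.2 CPM, though their reads can be shared. Immediate early and heat shock genes had 8 of 23 lower in hydrogen and gamma, 10 in silicon and 7 in iron (medians −0.42, −0.17, −0.46 and −0.23, and 0.27 with 3 lower in the remaining gamma cells and 5 lower in those of silicon), and −0.27 in mock over healthy, with FOSB at 269.8 CPM in mock and 53.1 to 168 CPM.

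Against healthy, medians went to the other side of 0 for interferon-stimulated genes in gamma (−0.45) and iron (−0.31), for cGAS-STING genes in gamma (−0.09), and for MHC class I genes in hydrogen (−0.07), gamma (−0.001, and 0.31 in its remaining cells) and iron (−0.16). They also did so for YAP and TEAD targets in silicon (−0.08), for ATF4 genes in gamma (−0.04, and 0.08 in its remaining cells) and iron (0.02), for pericyte markers in hydrogen (−0.61), gamma (−0.13, and 0.06 in its remaining cells) and iron (−0.35), and for CD68 in hydrogen (0.33) and gamma (0.25).

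Markers of other cell types were mostly absent. Of 12 epithelial markers only KRT8 and KRT18 were detected, KRT18 at 68.3 CPM in mock and 313, 91.0, 198 and 288 CPM (list medians 1.34, 0.26, 0.94 and 1.37, silicon at 1.897 in the remaining cells, and 0.20 in mock over healthy). Of 10 endothelial markers 1 was detected over mock, TEK, lower in all 4 (−1.92, −0.99, −1.06 and −1.57, silicon at −2.47 in the remaining cells), with a median of −0.38 for the 2 detected in mock over healthy. That median turned to 0.087 under median-of-ratios scaling. Of 14 blood and immune markers only CD68 was detected (−0.08, −0.16, −0.46 and 0.06, gamma at 0.38 in the remaining cells, and 0.41 in mock over healthy). Pericyte markers had medians of 0.10, 0.63, 0.05 (negative under both other scalings) and 0.18, and −0.16 in mock over healthy, with RGS5 at 13.8 CPM in mock and 26.2 to 46.3 CPM and MCAM at 115 CPM and 23.7 to 32.9 CPM. Of 12 fibroblast markers, 7 were lower in hydrogen, 5 in gamma and silicon and 6 in iron (medians −0.79, −0.39, −0.33 and −0.66, and −0.30 in mock over healthy), with S100A4 at 13.0 CPM in mock and 2.23 to 5.36 CPM and PDGFRA at 220.4 CPM and 69.3 to 118 CPM.

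Cluster 10 held 37 barcodes, all from iron (0.312% of that library), at a median of 779 UMIs, with the neurofilament gene NEFM at 809.5 CPM against 1.42 CPM in all other cells. If these were another cell type or free RNA, their share of UMIs from the fibroblast list was set to lie under 25% of that in other iron barcodes of the same UMI range, and over 80% if not. It was 0.583% (interval 0.513 to 0.661) against 2.10% in 9179 such barcodes and 1.52% in the nucleus-like ones among them, a relative level of 27.7%, which lies between both bounds and leaves another cell type and free RNA open. Genes under 1 CPM in one part of the other iron barcodes gave 6.26% of the cluster's UMIs (interval 6.03 to 6.49). In 1000 random sets of 37 barcodes from the rest the share was at most 0.748% for nucleus-like barcodes and 0.4897% for any barcodes. The cluster was itself formed from these counts and the random sets were not clustered, so a cluster of any origin could exceed them. This test therefore cannot decide on damaged fibroblasts. A rare state of the fibroblasts and biological explanations were not tested.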
